A study of Mus musculus with 17 samples.

How the data were processed

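Smart-seq2 RNA libraries of sorted mouse T cells were analysed, 17 in all, from the airway lumen, the mediastinal lymph node and Th2 culture. The authors deposited 1 table per library with RPKM (reads per kilobase of transcript, scaled to library size) for 24537 genes, each gene under 1 RefSeq transcript with its position on mm10. Per the submitters' processing notes, reads were aligned with HISAT2 2.0.4, quantified with HOMER and compared with DESeq2; their comparison tables were not analysed here. Of the genes, 22893 had the same transcript in the reporter and OTII tables, and 1644 had another transcript. No group test compared levels between the 2 kinds of mice. The scaling, the sums over gene lists and the check of widely expressed genes for missing reads did span both kinds. The 1644 genes were not left out of these steps, and how far the transcript used bears on them was not tested. In 29 genes the symbol had been spoilt in the symbol column, and the symbol in the annotation field was used.

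Low deposited RPKM values times transcript length were whole multiples of 1 read in every library (tolerance 0.1, checked below 100 reads, 100% whole). The size of that step gave the number of reads behind each table, 16.3 to 27.5 M (megareads) per library, and the reads behind each value. Counts read back in this way served for depth, for genes listed at 0 and for 1 further test.

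RPKM was scaled by 1 median-of-ratios factor per library over the 6796 genes with RPKM of at least 1 in all 17 libraries. Values in the text are scaled RPKM, as mean ± SD, unless stated. The comparisons of 2 groups numbered 3: airway against lymph node Th2 cells of reporter mice, and Notch1/2 knockout-labelled against wild type OTII cells in lymph node and in culture. An interaction contrast tested whether the knockout effect differed between lymph node and culture. Each used limma 3.58.1 (lmFit, eBayes with trend) in R 4.3.3 on log2(scaled RPKM + 1), two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. A gene was tested if its scaled RPKM was at least 1 in at least as many libraries as the smaller group holds. The words rose and fell are kept for genes past that threshold. The labels do not say that a replicate number links libraries of different groups, so no block entered the main test.

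Gene lists were written from general knowledge and fixed before the data were examined, as were the tests, most of the other settings tried and the rule for the genes named. There were 35 lists. Of these, 22 covered T cell programs and quality: Notch pathway, Notch targets, Th2, Th1 and cytotoxic, Th17, follicular helper, regulatory T, egress, homing, residency, naive and memory, early activation, checkpoint, cell cycle, MYC and mTORC1, cholesterol, lipid handling, glycolysis, oxidative phosphorylation, interferon response, ribosomal and stress. A further 12 held markers of T cells and of other cells, and 1 held sex-linked genes. Program lists with at least 5 tested members (21 per comparison) were tested with limma's camera at its preset correlation of 0.01, adjusted over the lists of a comparison. Beside it stand camera with an estimated correlation, and the number of members past the threshold when adjusted over all genes and when adjusted over the list alone. Limma's fry was run too, and its values are not printed. It called some lists that camera did not and missed some that camera called. The up to 200 genes with the smallest p called higher and lower in the airway were tested the same way in the lymph node knockout comparison, and the up to 200 called in each direction in the lymph node knockout comparison were tested in culture.

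Named genes came from a fixed rule. It took a fixed set in every comparison, among them Notch1, Notch2, Hes1, Dtx1, Gata3, Il4, Il5, Il13, Klf2, S1pr1, Ccr7 and Cd69. It added the 6 highest and 6 lowest fold changes among called genes whose groups do not overlap, with a mean of at least 5 in the higher group and without predicted genes, receptor segments, small RNAs, histones and pseudogenes. It also took the 3 members with the smallest p from each list that was called or had at least 2 called members, and in the interaction contrast the 5 smallest p. Other genes are marked as chosen after their values were seen.

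The test was tested on simulated data with the group sizes of each comparison and, for every gene alike, the median spread within its groups. It found 7.14% of genes changed 2-fold and 87.0% of genes changed 4-fold for the airway comparison. For the lymph node knockout comparison it found 100% and 100%, for culture 98.0% and 100%, and for the difference between them 85.9% and 100%. False calls were 8 of 95, 13 of 212, 32 of 228 and 12 of 197 calls. The simulation has no difference in spread between genes or between groups. The real libraries do differ in spread between genes (in culture Notch1 had an SE of 0.38 and did not pass at a log2 fold change of -3.14). Real airway replicates also correlated less with each other than lymph node reporter replicates did. These shares therefore do not bound what the test missed in the real data.

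Other settings tried were a pseudocount of 0.1 in place of 1, no filter, a filter on a mean of at least 5, RPKM as deposited, quantile normalization, 1 fit over all 17 libraries, library weights, eBayes without trend, replicate number as a block, 100 genes per signature set, and each library left out in turn. Settings added after the data were seen were limma voom on reads read back, airway replicate 3 alone against the lymph node, both reporter libraries numbered 2 left out, means of libraries that share a header number, a block of crossed numbers in culture, and signature sets without marker genes. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 prepared tables and figures. All 17 libraries were used. Hes1 did not reach the filter in any comparison and was not tested.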

Results

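RNA of sorted mouse T cells was sequenced with Smart-seq2, a protocol for small cell numbers, in 17 libraries that form 6 groups. The airway group (3 libraries) and the lymph node reporter group (3 libraries) hold Th2 cells of Gata3-YFP mice, in which a yellow fluorescent protein marks cells that express the Th2 regulator Gata3, from bronchoalveolar lavage and from the mediastinal lymph node that drains the lung. OTII mice, whose CD4 T cells carry a receptor for ovalbumin, gave wild type (3) and Notch1/2 knockout-labelled (4) Th2 cells of the same node. Both genotypes also gave Th2 cells grown from naive spleen T cells for 7 days on anti-CD3/CD28 with IL-4 and with antibodies that block IFN-γ and IL-12/23 (2 libraries each). The mice with sorted lymph node and airway cells had an allergen-driven airway inflammation. The labels do not say whether the replicates are separate animals.

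Read totals were 16.8, 17.1 and 17.1 M (megareads) in the airway libraries, and 17.5, 16.3 and 16.5 M in the lymph node reporter libraries. The wild type lymph node libraries held 18.9, 22.4 and 22.7 M reads and the knockout-labelled ones 22.4, 27.5, 24.1 and 19.9 M. In culture the totals were 21.0 and 21.4 M for wild type and 20.5 and 20.1 M for knockout-labelled cells. Airway libraries listed 14256, 14385 and 12317 of 24537 genes at 0, against 12177 to 12982 in the lymph node reporter libraries and 9432 to 10128 in the lymph node OTII libraries. Log2 values of replicate libraries correlated at r = 0.759 to 0.866 in the airway group, 0.931 to 0.957 in the lymph node reporter group and 0.981 to 0.995 in the lymph node OTII groups. These correlations run across genes, which are not independent replicates.

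The comparison of airway with lymph node Th2 cells in reporter mice asks which genes differ between cells that have left the node for the lung and cells still in it. Airway cells had lower values of proliferation genes such as Birc5, Aurkb and Mcm5 and of the granule protease gene Gzmb. They had higher values of the retention-linked genes Rgs1, Rgs2, Cd69 and Cxcr6, of the interleukin receptor genes Il1rl1 and Il7r, and of interferon response genes such as Irf7. The Notch targets Dtx1 and Gzmb were lower in the airway, while Notch1 and Notch2 themselves did not pass. Of the Th2 cytokine genes, Il4 and Il13, which basophils also make, fell along with the basophil genes Mcpt8 and Hdc, and Il5 did not pass. Macrophage transcripts such as Chil3 and Lyz2 were among the most abundant differences.

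**Figure D1:**
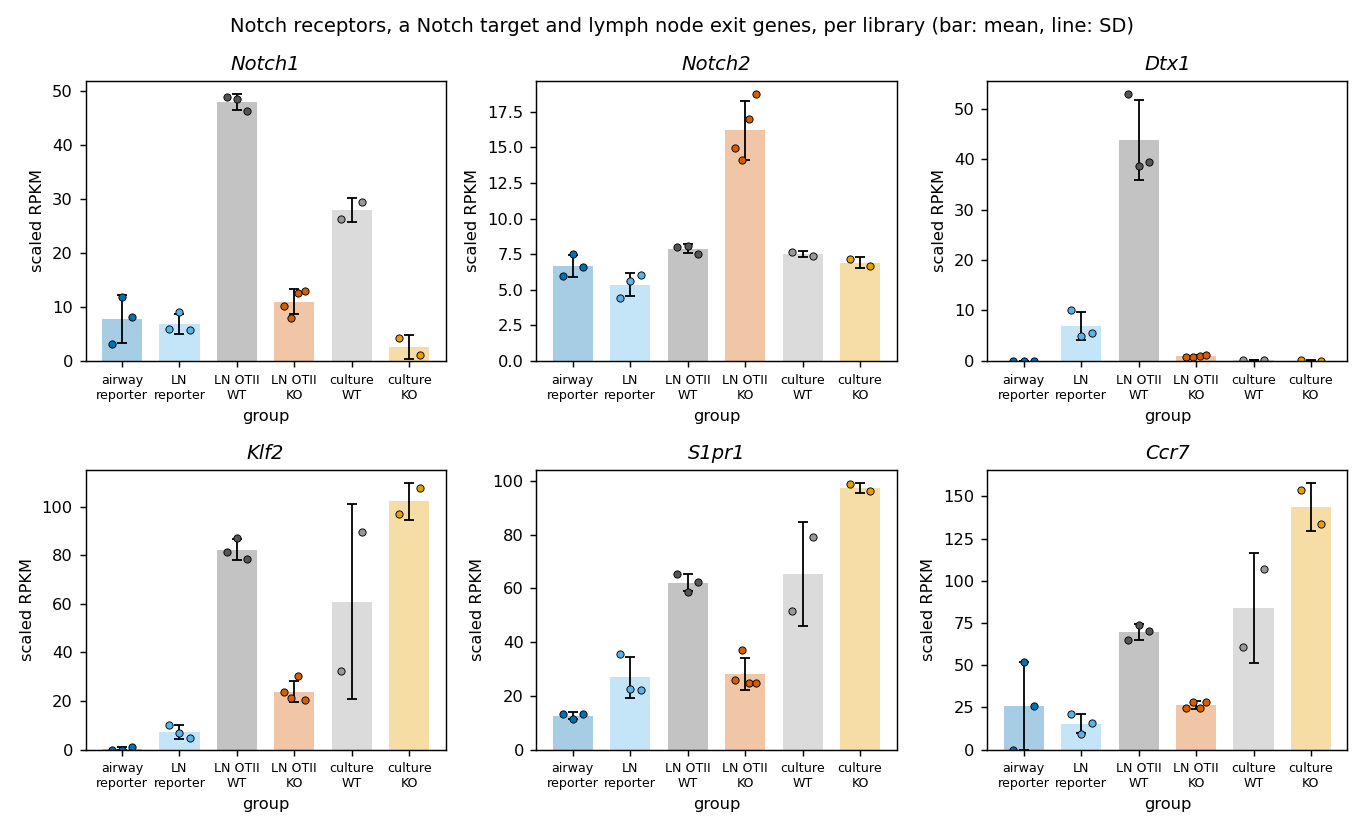
Scaled RPKM (vertical axis, linear, from 0) of Notch1, Notch2, Dtx1, Klf2, S1pr1 and Ccr7 in the 6 groups; bars are means, lines the SD and points single libraries. Dtx1 averaged 43.7 in wild type lymph node cells, 0.898 in knockout-labelled lymph node cells and 0.229 in wild type culture.

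The targeted receptor genes came first. Notch1 (NM_008714, chromosome 2, 26457902 to 26503822, mm10) averaged 6.88 ± 1.89 in the lymph node and 7.70 ± 4.42 in the airway (n = 3 each; log2 fold change 0.02, SE 0.53, adjusted p = 0.991). Notch2 (NM_010928, chromosome 3, 98013538 to 98150367) averaged 5.36 ± 0.817 and 6.69 ± 0.762 (log2 fold change 0.28, adjusted p = 0.779). Dtx1 (NM_008052, chromosome 5, 120680264 to 120711669), a Notch target that encodes an E3 ligase, had 799, 357 and 410 reads in the lymph node libraries and was listed at 0 in all 3 airway libraries (adjusted p = 0.0115). Zeros occur there among widely expressed genes too: of 3073 genes at 20 or more in all OTII libraries, 38, 49 and 2 were listed at 0 in the airway libraries and at most 1 in a lymph node reporter library. That call was lost without lymph node replicate 1, 2 or 3 (highest adjusted p = 0.0654).

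Gata3 (NM_008091, chromosome 2, 9857078 to 9878600), which drives Th2 identity, averaged 404 ± 55.7 in the lymph node and 417 ± 63.5 in the airway (adjusted p = 0.910). Il4 (NM_021283, chromosome 11, 53612461 to 53618665) fell from 474 ± 128 to 147 ± 49.6, a log2 fold change of -1.70 (SE 0.29, adjusted p = 0.0123). Il13 (NM_008355, chromosome 11, 53631323 to 53634702) fell from 93.2 ± 33.0 to 37.2 ± 9.42 (log2 fold change -1.27, SE 0.31, adjusted p = 0.0480). Il5 (NM_010558, chromosome 11, 53720794 to 53725103), the eosinophil growth factor gene, averaged 160 ± 83.5 and 154 ± 57.2 (adjusted p = 0.998). The call of Il4 was lost without lymph node replicate 2 or 3 (highest adjusted p = 0.0718), and that of Il13 without airway replicate 2 or 3 or lymph node replicate 2 or 3 (highest adjusted p = 0.198). In the same libraries the basophil genes Mcpt8 and Hdc fell from 132 to 13.6 and from 533 to 182, and basophils express Il4 and Il13 as well.

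Of the genes of lymph node exit and entry, Klf2 and Cd69 passed. Klf2 (NM_008452, chromosome 8, 72319062 to 72321654), a transcription factor that drives S1pr1, fell from 7.35 ± 2.82 to 0.340 ± 0.562 (log2 fold change -2.66, SE 0.54, adjusted p = 0.0252), with 399, 245 and 171 reads in the lymph node and 1, 0 and 34 in the airway. Cd69 (NM_001033122, chromosome 6, 129267325 to 129275369), whose product removes the S1pr1 receptor from the cell surface, rose from 72.1 ± 17.5 to 160 ± 14.8 (log2 fold change 1.16, SE 0.21, adjusted p = 0.0148). The sphingosine phosphate receptor gene S1pr1 (NM_007901, chromosome 3, 115710433 to 115715055) averaged 26.9 ± 7.65 and 12.7 ± 1.21 and did not pass (log2 fold change -1.002, SE 0.31, adjusted p = 0.111). Neither did the chemokine receptor gene Ccr7 (15.3 ± 5.72 and 25.9 ± 26.0, adjusted p = 0.875). The call of Klf2 was lost without airway replicate 2 or lymph node replicate 1, 2 or 3 (highest adjusted p = 0.130), and that of Cd69 without lymph node replicate 2 or 3 (highest adjusted p = 0.0753). Of 11 egress genes tested, 1 rose, 1 fell and 9 did not pass; adjusted over the list alone, 1 rose and 2 fell (median log2 fold change -0.14, camera adjusted p = 0.574).

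Among retention and homing genes, Rgs1, a damper of chemokine receptor signals, rose from 618 to 2819 and Rgs2 from 16.95 to 104. The chemokine receptor genes Cxcr6 (473 to 1363) and Ccr8 (178 to 502) and the adhesion gene Cd44 (22.1 to 93.4) rose as well. Of 12 residency genes 7 rose, 0 fell and 5 did not pass, and adjusted over the list alone 7 rose (median log2 fold change 1.09, camera adjusted p = 1.91e-06; adjusted p = 0.0690 with an estimated correlation). Fabp4, 1 of those 7, encodes a lipid carrier that macrophages also make. Of 21 homing genes 5 rose and 16 did not pass, and adjusted over the list alone 7 rose and 4 fell (median 0.24, camera adjusted p = 0.0206; adjusted p = 0.153 with an estimated correlation). The homing call was lost without airway replicate 1 (adjusted p = 0.173) or airway replicate 3 (adjusted p = 0.0610).

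Cell cycle genes were lower in the airway in all 24 members tested after scaling. Birc5, needed for chromosome segregation, fell from 183 to 29.6, the mitotic kinase gene Aurkb fell by 2.69 on the log2 scale, and the replication factor gene Mcm5 fell from 79.1 to 19.8. In the list 15 fell (3, 7 or 4 without lymph node replicate 1, 2 or 3) and 9 did not pass, and adjusted over the list alone 23 fell (median log2 fold change -2.36, camera adjusted p = 4.51e-18; adjusted p = 0.0690 with an estimated correlation). Glycolysis genes went the same way, with 5 of 17 fallen (3, 2 or 1 without lymph node replicate 1, 2 or 3) and 12 not past the threshold, and 8 fallen adjusted over the list alone (median -0.64, camera adjusted p = 1.91e-06; adjusted p = 0.0690 with an estimated correlation). The triose phosphate isomerase gene Tpi1 fell from 313 to 65.4. Among 21 oxidative phosphorylation genes only Ndufa4 fell (1 adjusted over the list alone, median -0.30, camera adjusted p = 0.0137; adjusted p = 0.296 with an estimated correlation). That list call was lost without airway replicate 1 (adjusted p = 0.0530), and the call of Ndufa4 with any 1 of the 6 libraries left out (highest adjusted p = 0.179).

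All 17 interferon response genes had positive log2 fold changes after scaling, as did all 13 macrophage genes tested, and macrophages express interferon response genes too. Irf7, which amplifies the interferon response, rose from 34.3 to 190. In the list 9 rose (5 without airway replicate 3, 3 or 1 without lymph node replicate 2 or 3) and 8 did not pass, and adjusted over the list alone 16 rose (median 1.75, camera adjusted p = 6.40e-14; adjusted p = 0.153 with an estimated correlation). Lipid handling genes rose in 5 of 13 cases (Fabp4, Cd36, Dgat1, Plin2 and Lpl) and fell in 1 (Scd2), and adjusted over the list alone 6 rose and 1 fell (median 1.01, camera adjusted p = 0.00203; adjusted p = 0.187 with an estimated correlation). Dgat1, which makes triglycerides, rose from 35.7 to 215; Fabp4 and Lpl, which macrophages also express, reached 16.7 and 12.7. Of 6 Notch target genes 2 fell (Dtx1 and Gzmb; 1 without any 1 of the lymph node libraries) and 4 did not pass, and adjusted over the list alone 4 fell (median -1.11, camera adjusted p = 9.77e-05; adjusted p = 0.0690 with an estimated correlation). Gzmb and Dtx1 had the lowest log2 fold changes of that list, so the 0 values of Dtx1 in the airway do not set the median. They do enter the camera test. Gzmb (NM_013542, chromosome 14, 56258836 to 56262334) fell from 505 ± 139 to 42.4 ± 11.4 (log2 fold change -3.54, SE 0.26, adjusted p = 3.28e-04). In the Notch pathway list 0 of 16 genes passed, over all genes or over the list alone (median 0.35, camera adjusted p = 0.0378; adjusted p = 0.273 with an estimated correlation). That call was lost without airway replicate 1 (0.140) or 2 (0.155), without lymph node replicate 1 (0.0718) or 3 (0.0929), and with RPKM as deposited (0.0962).

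Over all 10111 genes tested, 533 passed, of which 300 rose and 233 fell. With RPKM as deposited 229 rose and 317 fell, since the median log2 fold change of all genes is -0.20 there and -0.07 after scaling. Without lymph node replicate 1, 2 or 3 the count was 158, 163 or 113. Groups did not overlap in 2717 genes (26.9%), where chance gives 10%. The largest rises were in macrophage or myeloid genes. Chil3 (NM_009892, chromosome 3, 106147554 to 106167564), a chitinase-like gene of airway macrophages, rose from 0.0518 to 2985 ± 2170 (log2 fold change 11.20, SE 0.47, adjusted p = 1.92e-05). Lyz2, the myeloid lysozyme gene, rose from 16.7 to 1366 ± 646. The chemokine gene Ccl6 rose from 0.291 to 153 and the whey acidic protein gene Wfdc17 from 0.336 to 68.3; Car4 and Clec7a, listed at 0 in the lymph node libraries, reached 147 and 54.3. The largest falls were in the hormone gene Gcg, in Sccpdh, in the mitosis genes Ube2c, Cdc20 and Plk1, and in the hypoxia-induced gene Ankrd37 (log2 fold changes -5.13, -4.77, -4.45, -4.45, -4.20 and -4.10). Each of these falls lost its call without at least 1 of the lymph node libraries: Gcg without replicate 1 or 2, Plk1 without 1 or 3, and Sccpdh, Ube2c, Cdc20 and Ankrd37 without any 1 of them (highest adjusted p = 0.149), Ankrd37 also without airway replicate 3. Log2 fold changes moved to 5.89 or 8.55 for Lyz2 without lymph node replicate 1 or 2, to -6.44 for Gcg without lymph node replicate 3, to -6.04 for Sccpdh without airway replicate 3, and to -3.18 and -3.28 for Ube2c and Cdc20 without airway replicate 2.

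The comparison of knockout-labelled with wild type Th2 cells in the lymph node asks which genes depend on Notch there, under a series title that ties Notch to exit of Th2 cells from the node. The exit and naive state genes Klf2, S1pr1 and Ccr7 fell in knockout-labelled cells, along with 6 of 12 egress and 8 of 15 naive and memory genes in all, while Il7r rose. As lists these gave an adjusted p = 0.0841 and an adjusted p = 0.0902 with an estimated correlation. The Notch target Dtx1 fell to a mean below 1, and the granzyme genes Gzmb and Gzma fell. The NK cell gene Klrb1c fell as well, while the other tested gene of its list did not pass. Th1-linked genes such as Cxcr3 and Ccl5 rose, as did Il9r and Ccr8. Of the Th2 genes, Gata3 and Il4 fell, and Il5 and Il13 did not pass. The basophil gene Hdc fell too, from a level far below that of Il4. Some growth genes of the MYC and mTORC1 list and some stress genes fell, each list at an adjusted p = 0.231 with an estimated correlation.

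Notch1 fell from 47.9 ± 1.47 (n = 3) to 10.9 ± 2.31 (n = 4), a log2 fold change of -2.06 (SE 0.15, adjusted p = 5.49e-05). Notch2 rose from 7.88 ± 0.305 to 16.2 ± 2.09 (log2 fold change 0.95, SE 0.11, adjusted p = 5.95e-04). RPKM over a whole transcript does not show whether an exon is missing. Dtx1 fell from 43.7 ± 7.93 to 0.898 ± 0.216 (log2 fold change -4.55, SE 0.14, adjusted p = 1.31e-06). Gzmb fell from 117 ± 82.8 to 2.88 ± 1.15 (log2 fold change -4.56, SE 0.61, adjusted p = 0.00142; log2 fold change -5.45 without wild type replicate 1, the lowest of its group). Klrb1c, a gene of NK cells, which also express granzymes, fell too (4.14 to 0.268, kept with any 1 library left out). It was chosen after its values were seen. Of the 2 tested genes of the CD8 and NK list, the other 1 had a positive log2 fold change and did not pass. Among 6 Notch target genes 4 fell (Dtx1, Myc, Ccnd3 and Gzmb; 2 without wild type replicate 2) and 2 did not pass, and adjusted over the list alone 5 fell (median -0.78, camera adjusted p = 1.36e-04; adjusted p = 0.0841 with an estimated correlation). Of 18 Notch pathway genes 4 rose (Notch2, Rbpj, Maml2 and Psen2; 2 without wild type replicate 2 or 3 or knockout-labelled replicate 4), 1 fell (Notch1) and 13 did not pass. Adjusted over the list alone 5 rose and 1 fell (median 0.17, camera adjusted p = 0.0453; adjusted p = 0.231 with an estimated correlation). Rbpj, the DNA-binding partner of Notch, rose from 37.4 to 107. The call of Ccnd3 was lost without wild type replicate 2 (adjusted p = 0.0608). The pathway call was lost with RPKM as deposited (0.0524) and without wild type replicate 2 (0.0676) or 3 (0.0594) or knockout-labelled replicate 1 (0.0798), 3 (0.0740) or 4 (0.0515).

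Klf2 fell from 82.3 ± 4.27 to 23.9 ± 4.44 (log2 fold change -1.76, adjusted p = 5.90e-05) and S1pr1 from 62.2 ± 3.27 to 28.1 ± 6.06 (log2 fold change -1.14, adjusted p = 9.13e-04). Ccr7 (NM_001301713, chromosome 11, 99144199 to 99155077), which guides T cells into and within nodes, fell from 69.7 ± 4.49 to 26.4 ± 2.20 (log2 fold change -1.37, adjusted p = 3.12e-05). The groups did not overlap in any of these 3 genes, as in 3396 of all 10869 genes tested (31.2%). Each of the 3 kept its call with any 1 library left out. Of 12 egress genes 6 fell (among them these 3, S1pr4 and Cxcr4) and 6 did not pass, and adjusted over the list alone 6 fell (median -0.36, camera adjusted p = 5.73e-05; adjusted p = 0.0841 with an estimated correlation). Cd69 did not pass (log2 fold change 0.10, adjusted p = 0.789). Naive and memory genes fell in 8 of 15 cases and rose in 1 (Il7r), with 6 not past the threshold. Adjusted over the list alone 2 rose and 10 fell (median -0.59, camera adjusted p = 8.36e-05; adjusted p = 0.0902 with an estimated correlation). The genome organiser gene Satb1 fell from 98.6 to 30.0.

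Gata3 fell from 55.97 ± 5.51 to 40.3 ± 4.51 (log2 fold change -0.47, adjusted p = 0.0169) and Il4 from 44.7 ± 4.75 to 19.7 ± 8.24 (log2 fold change -1.24, adjusted p = 0.0207). Hdc, the 1 gene of the mast cell and basophil list tested, fell too (2.09 to 0.189, kept with any 1 library left out). It was chosen after its values were seen, and basophils express Il4. That list summed to only 2.07, 2.59 and 1.99 in the wild type lymph node OTII libraries. In the lymph node reporter libraries it summed to 559, 570 and 881, and Il4 averaged less than that. So little basophil RNA beside Il4 at 44.7 argues against basophils as the source of the whole Il4 fall. The call of Gata3 was lost without wild type replicate 2 or knockout-labelled replicate 4 (highest adjusted p = 0.0853), and that of Il4 without wild type replicate 1, 2 or 3 or knockout-labelled replicate 3 (highest adjusted p = 0.0868). Il5 (log2 fold change 0.38, adjusted p = 0.186) and Il13 (0.59, adjusted p = 0.349) did not pass. Of 17 Th2 genes 2 rose (Ccr8 and Il4ra), 8 fell (4 without wild type replicate 2, 5 without wild type replicate 3 or knockout-labelled replicate 3) and 7 did not pass, and adjusted over the list alone 3 rose and 8 fell (median -0.26, camera adjusted p = 0.174). The chemokine receptor gene Ccr8 rose from 21.2 to 85.6. Th1 and cytotoxic genes rose in 6 of 12 cases (3 without wild type replicate 2 or 3), fell in 2 (Gzma and Gzmb) and did not pass in 4, with the same counts adjusted over the list alone (median 0.59, camera adjusted p = 0.0289; adjusted p = 0.231 with an estimated correlation). This call was lost without knockout-labelled replicate 2 (adjusted p = 0.0612). Cxcr3, a receptor of Th1 cells, rose from 60.7 to 207, Ccl5 from 3.16 to 60.2, and the Th1 regulator gene Tbx21 by 1.08 on the log2 scale.

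Among 16 MYC and mTORC1 genes 9 fell (5 without wild type replicate 2 or 3), 1 rose and 6 did not pass, and adjusted over the list alone 1 rose and 12 fell (median -0.52, camera adjusted p = 1.23e-05; adjusted p = 0.231 with an estimated correlation). The nucleolar helicase gene Ddx21 fell by 0.78 on the log2 scale. Stress genes fell in 5 of 8 cases (3 without any 1 wild type library or knockout-labelled replicate 1 or 4) and did not pass in 3, with 5 fallen adjusted over the list alone (median -0.49, camera adjusted p = 7.11e-04; adjusted p = 0.231 with an estimated correlation). Cell cycle genes fell in 4 of 24 cases (1 without any 1 wild type library or knockout-labelled replicate 3 or 4, 10 without knockout-labelled replicate 2) and did not pass in 20, with 4 fallen adjusted over the list alone (median -0.21, camera adjusted p = 8.36e-05; adjusted p = 0.409 with an estimated correlation). Of 21 oxidative phosphorylation genes 1 fell (Atp5b, lost without wild type replicate 2 or 3), and 1 adjusted over the list alone (median -0.14, camera adjusted p = 0.00149; adjusted p = 0.320 with an estimated correlation). Of 22 ribosomal genes 1 fell (Rpl27, lost without wild type replicate 1 or 2 or knockout-labelled replicate 3 or 4), and 0 adjusted over the list alone (median -0.18, camera adjusted p = 0.00308; adjusted p = 0.471 with an estimated correlation). Follicular helper genes fell in 3 of 14 cases (5 without knockout-labelled replicate 4) and did not pass in 11, and adjusted over the list alone 2 rose and 5 fell (median -0.37, camera adjusted p = 0.0438; adjusted p = 0.546 with an estimated correlation). The follicular helper call was lost with RPKM as deposited (0.0613) and without wild type replicate 1 (0.139) or knockout-labelled replicate 1 (0.112), 2 (0.0678) or 3 (0.0543).

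Over all 10869 genes tested 1965 passed, with 1130 risen and 835 fallen. The count was 1008 without wild type replicate 2, 1045 without wild type replicate 3 and 1303 without knockout-labelled replicate 4. The largest rises were Ccl5, Il9r (4.78 to 52.6), the calmodulin-binding gene Nrgn (7.99 to 67.6), Klk1b27, Wnt10a and Ifitm10. The largest falls after Gzmb and Dtx1 were Gpr183 (16.9 to 0.468), a receptor that positions lymphocytes by oxysterols, Angptl2 (38.7 to 3.17), Fam20a (13.1 to 0.404) and Gzma (32.7 to 2.15). The ligand-activated transcription factor gene Ahr fell from 14.4 to 1.49, and the integrin gene Itgae rose from 2.58 to 12.3.

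**Figure D2:**
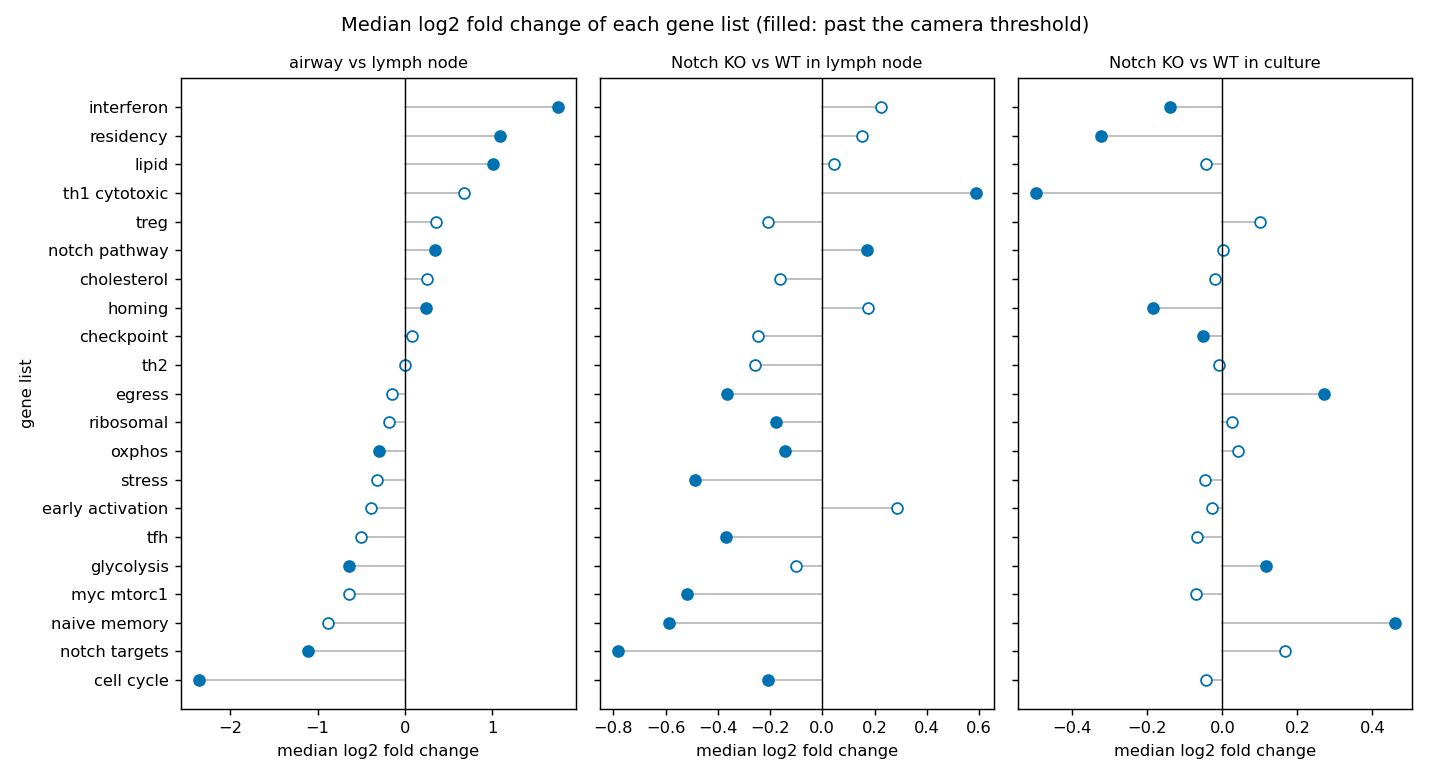
Median log2 fold change (horizontal axis, scale differs by panel) of each gene list in the airway, lymph node knockout and culture knockout comparisons; filled points passed camera at its preset correlation. Egress genes had a median of -0.36 in the lymph node knockout comparison and 0.27 in culture.

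The comparison of the same genotypes after 7 days of Th2 culture asks what the knockout changes outside the node. Values of Notch1 and of the granzyme gene Gzmb were lower in knockout-labelled cultures, but no single gene passed. The log2 fold changes of the exit and naive genes Klf2 and Ccr7 were positive, but only 0.19 and 0.42 without wild type replicate 1. As a set, Th1 and cytotoxic genes were lower and naive and memory genes higher than other genes at the preset correlation, with an adjusted p = 0.480 and an adjusted p = 0.530 with an estimated correlation. Limma called 0 of 10968 genes, with 256 at an unadjusted p under 0.05, and voom called 2. Notch1 did not pass at a log2 fold change of -3.14, so a count of 0 does not show that changes of that size are absent. Leaving out wild type replicate 2, knockout-labelled replicate 1 or knockout-labelled replicate 2 gave 2, 60 or 65 genes, where the lone library of a group is assumed to vary like the others.

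In culture Notch1 averaged 27.9 ± 2.22 in wild type and 2.64 ± 2.24 in knockout-labelled cells (n = 2 each; log2 fold change -3.14, SE 0.38, adjusted p = 0.333; Notch1 passed at -3.81 or -2.46 without knockout-labelled replicate 1 or 2). Notch2 averaged 7.51 ± 0.198 and 6.90 ± 0.365 (log2 fold change -0.11, SE 0.16, adjusted p = 0.9997). Dtx1, at 0.229 and 0.0554, was below the filter and not tested. Klf2 averaged 60.9 ± 40.3 and 102 ± 7.55 (log2 fold change 0.91, and 0.19 without wild type replicate 1), S1pr1 65.3 and 97.4, Ccr7 83.9 and 144, and Gata3 62.6 and 86.2, and none of these passed. Neither did Gzmb (1657 ± 216 and 733 ± 113, log2 fold change -1.18; it passed at -1.34 without knockout-labelled replicate 2). The smallest p values among genes with higher and lower values did not pass either, with Slc15a2, a peptide transporter gene listed at 0 in both wild type libraries and read 158 and 228 times in the others, at an adjusted p of 0.333.

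The 13 Th1 and cytotoxic genes had a median of -0.50 (camera adjusted p = 2.35e-12, and adjusted p = 0.480 with an estimated correlation), and 7 fell adjusted over the list alone. All 3 tested genes of the CD8 and NK marker list were negative there too (median -0.78), and 2 fell adjusted over that list alone. The 15 naive and memory genes had a median of 0.46 (camera adjusted p = 2.35e-10; adjusted p = 0.530 with an estimated correlation), and 2 rose adjusted over the list alone. The 12 egress genes had a median of 0.27 (2.76e-05; adjusted p = 0.530 with an estimated correlation), with Klf2, S1pr1 and Ccr7 on the higher side (log2 fold changes of 0.19, 0.30 and 0.42 without wild type replicate 1). The 10 residency genes had a median of -0.33 (2.56e-06; adjusted p = 0.480 with an estimated correlation), and the 20 homing genes one of -0.19 (8.65e-04; adjusted p = 0.480 with an estimated correlation), with 3 homing genes fallen adjusted over the list alone. Glycolysis (17 genes, median 0.11, camera adjusted p = 0.0155), interferon response (14 genes, median -0.14, 0.0348) and checkpoint genes (9 genes, median -0.05, 0.0492) passed with 0 members called adjusted over the list alone, and with an estimated correlation their adjusted p was 0.853, 0.766 and 0.530. The glycolysis call was lost without wild type replicate 1 (0.985, direction reversed) or knockout-labelled replicate 1 (0.840). The interferon call was lost without wild type replicate 1 (0.629) or 2 (0.0672) or knockout-labelled replicate 2 (0.566), and the checkpoint call without wild type replicate 2 (0.270) or knockout-labelled replicate 2 (0.222). The 6 Notch target genes had a median of 0.17, a mean of -0.01 and an upward test (adjusted p = 0.602), and the 19 Notch pathway genes a median of 0.00, a mean of -0.14 and a downward test (0.8287).

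Whether the knockout effect itself differs between lymph node and culture was tested as an interaction. The knockout effect lay lower in the node than in culture, past the threshold, for Klf2, S1pr1, Ccr7 and the positioning receptor gene Gpr183. The same held for some other egress and naive and memory genes. As lists these gave an adjusted p = 0.0863 and an adjusted p = 0.118 with an estimated correlation. Il9r had a positive difference. Of the targeted genes, Notch2 differed and Notch1 did not pass.

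Notch1 differed by 1.08 on the log2 scale (SE 0.43, adjusted p = 0.209; 1.75 without knockout-labelled culture replicate 1, where it passed, and 0.41 without replicate 2) and Notch2 by 1.05 (adjusted p = 0.00563). Among the 11508 genes tested 442 passed, 270 with a positive and 172 with a negative difference. Of the 442, 77 were below the filter in culture, where no knockout effect could be measured, so their difference restates the lymph node fold change. The count was 285 or 256 without wild type lymph node replicate 2 or 3, 195 without wild type culture replicate 1 and 212 without knockout-labelled culture replicate 2. The genes with the smallest p were Dtx1 (-4.33, adjusted p = 9.64e-06), the epithelial-type transcription factor gene Grhl1 (-2.97, 2.44e-05) and the pseudokinase gene Prag1 (-2.70, 3.39e-05), all 3 below the filter in culture, followed by Gpr183 (-3.77, 4.97e-05) and Il9r (3.18, 4.97e-05). Klf2 (-2.67, adjusted p = 0.00685), S1pr1 (-1.74, 0.00514) and Ccr7 (-2.19, 0.00118) passed with every library left out in turn, Klf2 at -1.95 without wild type culture replicate 1 and -3.38 without replicate 2. The call of Gata3 (-0.93, 0.0186) was lost without wild type culture replicate 1 or knockout-labelled culture replicate 1 or 2 (highest 0.0940).

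Notch targets differed as a list (7 genes, median -0.95, camera adjusted p = 2.43e-06) and passed with an estimated correlation too (adjusted p = 0.0249); 1 gene passed over all genes, Dtx1, which was below the filter in culture, and 5 were lower adjusted over the list alone. Egress genes (12 genes, median -0.63, camera adjusted p = 2.43e-06) had 5 lower (3 without wild type lymph node replicate 2, wild type culture replicate 1 or knockout-labelled culture replicate 1 or 2) and 7 lower adjusted over the list alone, with an adjusted p = 0.0863 with an estimated correlation. Naive and memory genes (15 genes, median -0.95, 6.44e-08) had 7 lower, and 1 higher and 11 lower adjusted over the list alone, with an adjusted p = 0.118 with an estimated correlation. Th1 and cytotoxic genes (16 genes, median 1.02, 2.44e-05) had 4 higher, and 9 higher and 2 lower adjusted over the list alone, again at an adjusted p = 0.118 with an estimated correlation. MYC and mTORC1 genes (16 genes, median -0.44, 3.27e-04) had 2 lower (0 or 1 without most single libraries, 5 without wild type lymph node replicate 1), and 1 higher and 6 lower adjusted over the list alone, at an adjusted p = 0.400 with an estimated correlation.

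**Figure D3:**
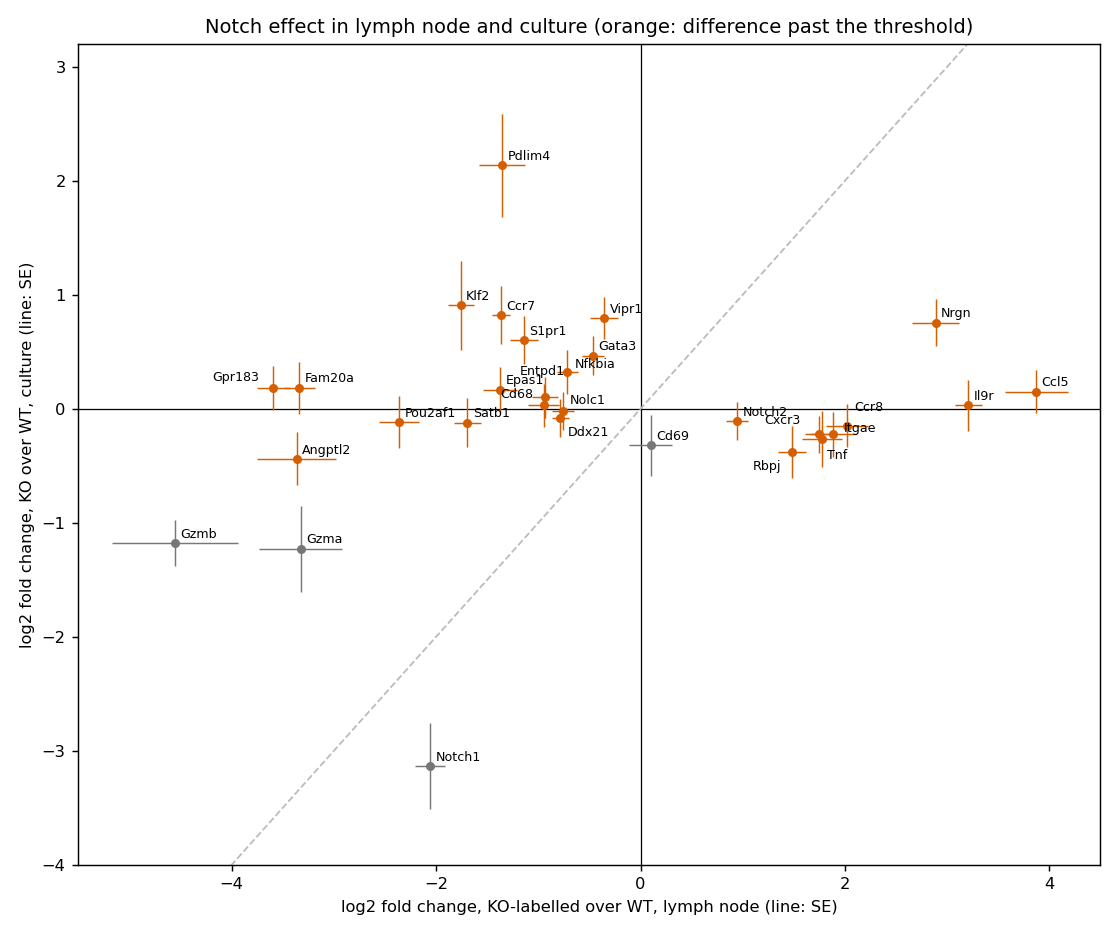
Log2 fold change of knockout-labelled against wild type cells in the lymph node (horizontal axis) and in culture (vertical axis) for named genes, with lines for the SE and a dashed line where both are equal; orange points passed the interaction test. Klf2 lies at -1.76 and 0.91 (0.19 in culture without wild type replicate 1), and grey Notch1 at -2.06 and -3.14.

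The last comparison asks whether genes that differ between airway and lymph node also differ by genotype within the node; the libraries involved are not shared. Genes higher in the airway, among them Ccl5, Ccr8 and Il7r, were on balance higher in knockout-labelled lymph node cells. Genes lower in the airway were on balance lower there (camera p = 0.0877 with an estimated correlation). That set holds Klf2, Il4, Gzmb and Dtx1 and many cell cycle genes, such as Birc5, Aurkb and Mcm5. The cell cycle list had a median of -0.21 in the lymph node knockout comparison, with 23 of 24 genes negative. How much of the set's shift these genes carry was not tested.

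Of 148 airway-higher genes tested, 105 had a positive log2 fold change in knockout-labelled cells (median 0.19), and 46 rose and 12 fell (camera p = 2.51e-05, and p = 0.00475 with an estimated correlation). Of 189 airway-lower genes 161 had a negative one (median -0.23), and 7 rose and 50 fell (camera p = 4.13e-14; p = 0.0877 with an estimated correlation of 0.191). Among 9644 genes tested in both, 62 rose in both where 21.8 would overlap if the calls were independent, and 59 fell in both where 17.3 would. Opposite calls numbered 16 where 18.1 would overlap, and 7 where 20.9 would. Across genes, which are not independent replicates, the log2 fold changes correlated at Pearson r = 0.240 and Spearman rho = 0.251. With the genes of the macrophage and other marker lists left out of the sets, camera p was 1.41e-05 and 7.88e-14 at the preset correlation. Other myeloid genes, such as Ccl6, Wfdc17 and Clec7a, are not on those lists. These p values therefore do not show what the sets give without macrophage RNA.

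**Figure D4:**
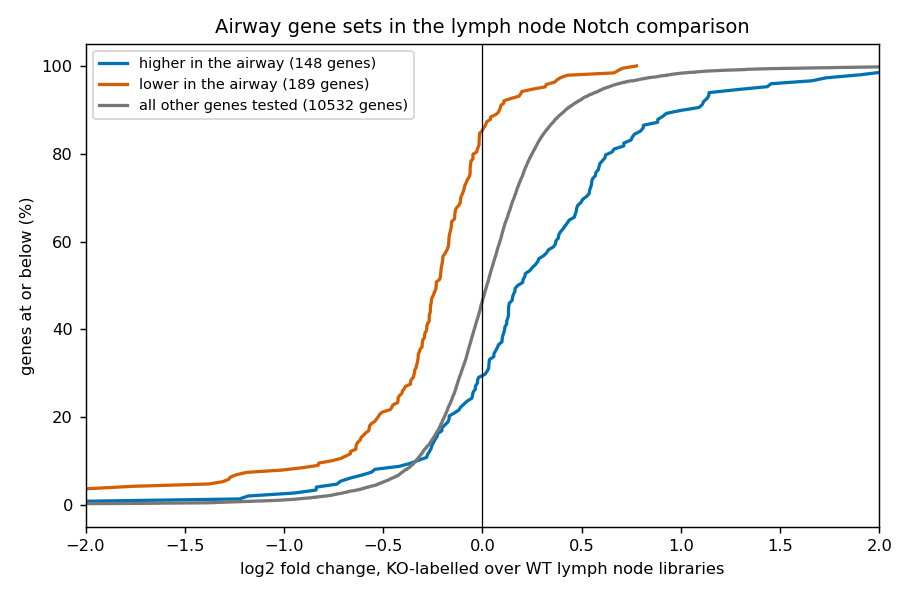
Cumulative percentage of genes (vertical axis) against log2 fold change of knockout-labelled over wild type lymph node cells (horizontal axis, shown from -2 to 2) for airway-higher genes, airway-lower genes and all other genes. The medians of the airway-higher and airway-lower genes are 0.19 and -0.23.

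The genes called in the lymph node knockout comparison were then tested in culture, Il9r and Klf2 among the genes in question. The 172 higher genes had a median of -0.01 in culture and a downward test (p = 0.0433; p = 0.252 with an estimated correlation). That call was lost without wild type lymph node replicate 2 (0.0646) or knockout-labelled lymph node replicate 1 (0.0615) or 2 (0.428). The 167 lower genes had a median of 0.00, 85 of them positive, and a downward test (camera p = 0.705, and p = 0.864 with an estimated correlation). Across 10490 genes the log2 fold changes of both knockout comparisons correlated at r = -0.0554 and rho = -0.125.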

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

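All tests of explanations and of other splits of the samples given here were chosen only after the results they bear on were seen.

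Macrophage genes were higher in the airway libraries. All 13 tested genes of the macrophage marker list had positive log2 fold changes and 9 passed (5 without any 1 of the lymph node libraries); their scaled RPKM summed to 3319, 7429 and 3257 in the airway libraries, 23.1 to 60.3 in the lymph node reporter libraries and at most 13.3 in the OTII libraries. Chil3 averaged 2985 and Lyz2 1366. A candidate explanation is RNA of airway macrophages in the sorted samples, although sorting on specific antibodies and YFP should remove such cells; the count of 13 restates the pattern and could only have counted against it, so it leaves this open. Whether the source was whole cells, attached cells or free RNA, and whether the T cells themselves took up or made any of these transcripts, was not tested and stays open, as does a difference between tissues.

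Cell cycle genes were lower in the airway libraries, with a median log2 fold change of -2.36. Airway replicates 1 and 2 listed more genes at 0 (14256 and 14385) than any lymph node reporter library. Airway replicate 3, at 12317, lay within the lymph node range of 12177 to 12982. Random lists matched on lymph node expression had a 1st percentile of -0.40 and a lowest median of -0.68. The list thus lay at the 0.01 percentile, the smallest that 10000 draws can give, which argues against weakly read genes being missed as the whole cause. Dilution of T cell RNA by RNA of other cells would lower T cell genes as well, and the T cell identity list had a median of 0.080 (quartiles -0.29 and 0.26), which argues against dilution as the whole cause. A difference in division between tissues, named by the design, stays open and was not tested, and a different mix of T cell states in the 2 sorts may contribute too.

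Egress genes were lower in knockout-labelled lymph node cells. A single library that stands apart would end the list's call when left out, but the camera adjusted p was at most 1.28e-04 with any 1 library left out. Libraries of shared origin, read from header numbers whose meaning is not stated, gave 4.00e-05 when averaged, which cannot tell for or against that cause. The list's median of -0.36 lay farther from 0 than in any other of the 35 splits (1 of 35, highest other 0.31), but the list was taken up because it had passed here, so this cannot exclude chance. Shared origin stays open, and so does genotype, named by the design, which was not tested apart from any difference in the state or mix of sorted cells, and with an estimated correlation the list's adjusted p was 0.0841.

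The splits of the 7 lymph node OTII libraries take them as separate samples, which the labels do not state. On that condition no other of the 35 splits called as many genes as the real 1965 (highest other 252). The medians of the airway-higher genes (0.19, highest other 0.17) and airway-lower genes (-0.23, highest other 0.22) were also farthest from 0 in the real split. Camera p was smaller in another split for each set. For airway-higher genes it was 1.53e-05 against 2.51e-05, and for airway-lower genes 6.34e-15 against 4.13e-14. A share of 1 of 35 is the smallest these splits can give. They were chosen after the results were seen and not adjusted for each other, so chance is not excluded. For airway against lymph node the 10 splits are too few for a share under 0.05; the real split, 1 of 10, gave 533 genes and the highest other 0.

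Single libraries stood far from the rest of the knockout-labelled lymph node group in 7 of the 81 values looked at, where chance gives about 1 in 20. In replicate 2 these were Cxcr3 at 160, Rbpj at 134, S1pr1 at 37.1 and the number of genes listed at 0, 9432. In replicate 4 they were Gzmb at 1.16, Hspe1 at 74.6 and Isg15 at 15.5.

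The interaction test between lymph node and culture called 442 of all 11508 genes tested. The 98 genes looked at here were named partly for large lymph node fold changes or small p values, some from the interaction test itself. A high share among them was therefore built in. The knockout effect differed between lymph node and culture in 34 of the 98. For 8 of these the gene was below the filter in culture (Dtx1 had 15, 19, 7 and 1 reads there), so the value restates the lymph node fold change and does not show an effect that depends on the setting: Dtx1 (-4.33), Grhl1 (-2.97), Prag1 (-2.70), Ahr (-2.52), Cebpa (-2.24), Klk1b27 (2.99), Ifitm10 (2.95) and Il2 (2.04). The other 26 were tested in both settings. Lymph node effects lay below culture effects for Gpr183 (-3.77), Fam20a (-3.52), Pdlim4 (-3.49), Angptl2 (-2.92), Klf2 (-2.67), Pou2af1 (-2.25), Ccr7 (-2.19), S1pr1 (-1.74), Satb1 (-1.57), Epas1 (-1.54), Vipr1 (-1.15), Entpd1 (-1.04), Nfkbia (-1.04), Cd68 (-0.98), Gata3 (-0.93), Nolc1 (-0.74) and Ddx21 (-0.70), all as differences of log2 fold changes. They lay above culture effects for Ccl5 (3.72), Il9r (3.18), Ccr8 (2.17), Nrgn (2.13), Itgae (2.10), Tnf (2.04), Cxcr3 (1.97), Rbpj (1.87) and Notch2 (1.05).

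The same difference passed for 11 gene lists. Their median differences were -0.95 for Notch targets, -0.63 for egress, -0.95 for naive and memory, 1.02 for Th1 and cytotoxic, -0.44 for MYC and mTORC1, -0.42 for follicular helper, -0.31 for stress, -0.23 for glycolysis, -0.23 for ribosomal, -0.20 for cell cycle and -0.18 for oxidative phosphorylation genes. The first 5 of these have their tests among the results above. For the others the camera adjusted p was 0.0331 for follicular helper, 0.0112 for stress, 0.0301 for glycolysis, 0.00530 for ribosomal, 0.0104 for cell cycle and 0.00645 for oxidative phosphorylation genes, and with an estimated correlation 0.464, 0.380, 0.464, 0.464, 0.464 and 0.407. The follicular helper call was lost with RPKM as deposited (0.0566) and without lymph node wild type 1 (0.0837), lymph node knockout-labelled 1 (0.103), culture wild type 1 (0.0710) or culture knockout-labelled 1 (0.0550). The glycolysis call was lost without lymph node wild type 2 (0.0564), culture wild type 1 (0.376) or culture knockout-labelled 1 (0.299), the cell cycle call without culture wild type 2 (0.126) or culture knockout-labelled 2 (0.252). The ribosomal call was lost without culture wild type 1 (0.0536) or culture knockout-labelled 1 (0.0611), the oxidative phosphorylation call without culture knockout-labelled 2 (0.0636).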

How the results depend on the processing

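Chosen only after the results were seen were voom, airway replicate 3 alone, both reporter libraries numbered 2 left out, header number means, the crossed block and the sets without markers. Few reads limit what the values of a gene can show, as for Klf2 in the airway at 1, 0 and 34 reads. Total reads were close between airway and lymph node reporter libraries, so the number of reads does not account for that difference. Airway replicates 1 and 2, with 1 and 0 reads of Klf2, also listed 38 and 49 of 3073 widely expressed genes at 0. Transcripts missed in these libraries are therefore not excluded. The spread within groups limits the airway comparison, where the simulated test found 7.14% of 2-fold changes. That simulation gave both groups the same spread, so this share does not show what the airway libraries alone contribute. Where 1 fit covers all 17 libraries the spread is shared between groups, and where libraries are left out fewer remain, which bears on the counts there; the cause was not tested for the others.

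For airway against lymph node (533 genes) the count was 224 without a filter, 2705 in 1 fit over 17 libraries, 246 without trend, 233 with voom, 0 with airway replicate 3 alone (1920 at an unadjusted p under 0.05; a group of 1 library, whose spread comes from the other group, so the count says little) and 128 without both libraries numbered 2. For the knockout in lymph node (1965 genes) it was 353 in 1 fit over 17 libraries, 3518 with library weights and 636 with the replicate block. In culture (0 genes) it was 65 with the replicate block, 2 with voom and 8 with the crossed block. For the difference between both (442 genes) it was 79 in 1 fit over 17 libraries, 139 with the replicate block and 257 with header number means. Same-numbered libraries correlated after removal of group means at 0.00493 to 0.0272 between airway and lymph node, -0.323 to -0.0640 in lymph node OTII and -0.191 in culture. Each airway and lymph node reporter library did so best with its own number, and Y-linked genes were read only in the 2 numbered 2, a hint from the data that numbers mark a shared source there; the replicate block gave 403 genes. With 1 library left out, the counts of the 4 comparisons ranged, in the same order, from 113 to 554, from 1008 to 2716, from 0 to 65 and from 195 to 555. The set of airway-lower genes in the lymph node knockout comparison had p = 0.0877 with an estimated correlation, and p ranged from 2.27e-16 to 1.99e-11 with 1 library left out; for airway-higher genes that range was 1.02e-05 to 1.33e-04. In culture the set of lymph node higher genes had p = 0.252 with an estimated correlation and 0.0729 with the replicate block (0.0145 to 0.428 with 1 library left out). At 100 genes per set its downward shift was larger (median -0.11, camera p = 0.00215 at the preset correlation). The set of lower genes had p = 0.864 with an estimated correlation and reversed at 100 genes per set (p = 0.110) and without knockout-labelled replicate 3 (range 0.299 to 0.935).

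Named genes that reversed had not passed. In the airway comparison Ccr7 was 0.25 with library weights and 0.78 with replicate 3 alone (-1.59 to 1.27 with 1 library left out). Gata3 was -0.095 as deposited, -0.093 with quantile normalization, -0.12 with weights, -0.045 with voom and -0.18 with replicate 3 alone (-0.074 to 0.16). Il5 was -0.14 as deposited, -0.075 with quantile normalization, -0.28 with weights, -0.082 with voom, -0.36 with replicate 3 alone and -0.43 without both libraries numbered 2 (-0.28 to 0.40). Notch1 was -0.0056 with a pseudocount of 0.1, -0.10 as deposited, -0.068 with voom and -0.15 without both libraries numbered 2 (-0.34 to 0.49). In lymph node Lyz2 was 0.041 with weights (-0.31 to 0.032) and Cd69 ranged from -0.16 to 0.27. In culture Il4 was 0.011 as deposited and 0.0044 with quantile normalization (-0.27 to 0.26), Cd69 ranged from -0.73 to 0.093, and the glycolysis list had an adjusted p of 9.56e-04 to 0.985.

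Of 75, 78, 33 and 16 named genes in the 4 comparisons, 37, 55, 19 and 13 kept direction and side of the threshold with every library left out, and 2, 37, 19 and 10 under every other setting. Of 9, 11, 8 and 11 list calls, 6, 8, 5 and 6 held with every library left out, and 0, 0, 0 and 1 under every other setting, the estimated correlation included.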

Other observations

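No test of an explanation is given here; the choice of values to show was made after they were seen, except for the lists.

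Wild type OTII cells held Dtx1 at 43.7 in the lymph node and 0.229 in culture, a pair of groups that was not compared by a test. Transcripts of basophils and mast cells were read in the reporter libraries. The sum over the mast cell and basophil list was 559, 570 and 881 in the lymph node, 276, 148 and 164 in the airway, and at most 16.3 in the OTII libraries. Mcpt8, a basophil protease gene, fell from 132 ± 13.5 in the lymph node to 13.6 ± 13.2 in the airway and Hdc, which makes histamine, from 533 to 182. The call of Mcpt8 was lost without lymph node replicate 1, 2 or 3 (highest adjusted p = 0.0617) and that of Hdc without lymph node replicate 1 or 3 (highest 0.0606). The glucagon gene Gcg had 2720, 2202 and 139 reads in the lymph node reporter libraries and 0, 0 and 24 in the airway libraries.

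Y-linked genes summed to 43.5 in airway replicate 2 and 58.1 in lymph node reporter replicate 2 and to 0 in all other libraries. Xist was 0.758 and 1.42 in those 2 and 9.23 to 25.4 in the other reporter libraries. In the sex list 1 gene was tested in each comparison and 0 passed.

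In the airway comparison the remaining lists did not pass camera. Members risen and fallen were 2 and 4 of 21 for Th2 (2 and 5 adjusted over the list alone; median 0.00, mean -0.16, downward test, adjusted p = 0.867), 3 and 0 of 13 for follicular helper (3 and 4; 0.867) and 2 and 1 of 12 for Th1 and cytotoxic (4 and 1; 0.172). They were 2 and 1 of 11 for regulatory T (3 and 1; 0.153), 1 and 2 of 14 for naive and memory (1 and 3; 0.0975), 2 and 2 of 15 for early activation (2 and 3; 0.428) and 3 and 1 of 10 for checkpoint (5 and 3; median 0.08, mean -0.00, upward test, 0.204). They were 1 and 1 of 15 for MYC and mTORC1 (2 and 4; 0.172), 0 and 0 of 18 for cholesterol (2 and 0; 0.0975), 0 and 0 of 22 for ribosomal (0 and 0; 0.172), 1 and 0 of 7 for stress (1 and 3; 0.304) and 0 and 0 of 2 for Th17, which was too small for camera.

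In the lymph node knockout comparison members risen and fallen were 6 and 3 of 19 for homing (6 and 3 adjusted over the list alone; adjusted p = 0.195), 4 and 2 of 12 for residency (5 and 2; 0.510), 1 and 3 of 11 for regulatory T (1 and 4; 0.0680) and 6 and 2 of 18 for early activation (7 and 3; 0.253). They were 1 and 4 of 9 for checkpoint (2 and 4; 0.0833), 1 and 1 of 18 for cholesterol (1 and 1; 0.140), 3 and 2 of 12 for lipid handling (3 and 2; 0.639), 1 and 2 of 17 for glycolysis (1 and 2; 0.253), 4 and 2 of 13 for interferon response (5 and 2; 0.253) and 0 and 1 of 1 for Th17.

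In culture no member of any list passed over all genes. The adjusted p of lists not named above was 0.602 for Th2 (17 genes), 0.8287 for follicular helper (11 genes; median -0.07, mean 0.02, downward test), 0.665 for regulatory T, 0.844 for early activation, 0.245 for cell cycle, 0.120 for MYC and mTORC1, 0.424 for cholesterol, 0.602 for lipid handling, 0.466 for oxidative phosphorylation, 0.197 for ribosomal and 0.595 for stress genes. No Th17 gene was tested there.

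For the difference between lymph node and culture, lists that did not pass were Notch pathway (19 genes, 2 higher, adjusted p = 0.0535), Th2 (20 genes, 1 higher and 2 lower, 0.0880), homing (24 genes, 4 higher and 2 lower, 0.103) and residency (12 genes, 1 higher and 1 lower, 0.0856). The others were regulatory T (0.0952), early activation (4 higher and 1 lower, 0.127), checkpoint (2 lower, 0.368), cholesterol (0.340), interferon response (0.0856) and lipid handling (median -0.02, mean 0.12, upward test, 0.538).

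Marker lists were read as counts of members risen and fallen. In the airway comparison these were 1 and 0 of 12 for T cell identity (Cd2), 1 and 0 of 2 for CD8 and NK cells (Klrk1, listed at 0 in the lymph node), 0 and 1 of 7 for B cells (Cd79b), 0 of 2 for plasma cells, 9 and 0 of 13 for macrophages, 2 and 0 of 6 for dendritic cells, 0 of 1 for eosinophils, 1 and 0 of 1 for neutrophils (S100a8), 0 and 2 of 3 for mast cells and basophils, 0 of 1 for epithelium and 0 of 2 for stroma, with 0 erythroid genes tested. In the lymph node knockout comparison they were 1 and 0 of 12 for T cell identity, 0 and 1 of 2 for CD8 and NK cells, 0 of 6 for B cells, 0 of 1 for plasma cells, 0 and 2 of 3 for macrophages, 1 and 0 of 5 for dendritic cells, 0 of 1 for eosinophils, 0 and 1 of 1 for mast cells and basophils, 1 and 1 of 3 for epithelium, 0 of 1 for stroma and 0 of 1 for erythroid cells, with 0 neutrophil genes tested. In culture 0 members of any marker list passed.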
